A study of Mus musculus with 7 samples.

How the data were processed

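ATAC-seq libraries of HopX-positive cells sorted from mouse brain were analysed at 3 ages, with 2 libraries at embryonic day 15 (E15), 3 at postnatal day 3 (P3) and 2 of adult animals. Groups and replicate numbers were taken from the sample titles. For each library the authors deposited a list of aligned reads and a list of peaks. The genome build is mm9 and bcl2fastq was used, per the submitters' processing notes. The aligner is not given in the sources used here. Column 5 of each deposited read list is a score, the mapping quality of the read, with values up to 42. No minimum of mapping quality is seen in the deposited reads, and reads that repeat a position are kept. Read names show 2 sequencing runs in every library. Peaks were called per library with MACS 2.1.1.20160309 in single-end mode as broad regions, at q limits of 0.005 and 0.1, without a control and with 1 read kept per position, per the file headers. The total reads in the peak headers equal the deposited reads in all 7 libraries. The peak lists give the pileup signal, a fold enrichment (a ratio to the local background) and −log10 of p and q values, per the file headers. These values are the authors' own for each peak and were used here only to describe, rank and filter peaks within a list.

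Read ends were moved by 4 bases on the plus strand and 5 on the minus strand to the centre of the Tn5 insertion. The deposited reads were tested for an earlier shift: the most frequent distance between read ends of opposite strands was 8 bases in all 7 libraries, the spacing of unshifted reads with a 9-base overhang. Reads of a library with the same chromosome, start, end and strand counted once. Read lengths differ between the sequencing runs, so the same molecule read in both runs can count more than once. Peaks overlapping by at least 1 base were merged, and regions with peaks of at least 2 libraries on the 19 autosomes were kept, since the sex of the animals is not in the labels. Fragment lengths came from mate pairs with a mapping quality of 30 or more in both mates.

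Regions with at least 10 reads in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3. Reads were scaled by the trimmed mean of M values (trims of 0.3 and 0.05), shown as CPM, the reads of a region relative to the scaled library, and weighted with voom, with all 7 libraries in 1 fit. The design fixed before the data were examined named a count test on the number of reads per region. It named limma-voom on the same reads if a check of units accepted no deposited values as whole-number counts. The deposited files hold reads and no column of counts that this check accepted. Limma-voom was therefore used, on whole numbers of reads per region counted here, and the count test was not run. The F test across the 3 ages was computed from the weights of each region. It took the place of the F of limma, which uses 1 correlation for all regions, after 2 counts of that F had been seen, 3 over 3 contrasts of group means and 13 over 2 contrasts. With an intercept in the design that F gave 0. p-values were adjusted by the Benjamini-Hochberg method at a limit of 0.05. The text names regions by a rule fixed before the data were examined: adjusted p under 0.05, an absolute log2 fold change of at least 1, every library of 1 age above every library of the other, and at most 3 regions each way by p. Library measures were compared by exact two-sided permutation tests, 63 in all (21 measures, 3 comparisons), and no such test can reach 0.05 with these group sizes. Peak overlap by chance came from 20 random shifts of peak positions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

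The fit was tested on simulated data with the means and library sizes of the 24963 tested regions, in 10 draws per comparison with 200 changed regions each. Regions of similar mean shared 1 spread, pooled within ages. Of 4-fold changes, 6.80% were recovered for P3 against E15, 15.4% for adult against P3 and 1.80% for adult against E15. Of 16-fold changes, 19.0%, 26.4% and 8.00% were recovered. Of all calls in these simulations, 13 of 235, 20 of 346 and 1 of 74 were false. These shares hold for the pooled spread alone and do not give the rate of false calls in the real data. With little noise and low means raised, all 200 changed regions were recovered, beside 16 false calls. Wilson 95% intervals of the shares of reads of mapping quality 30 or more, in regions and on the mitochondrial genome extend at most 0.0596 percentage points either side. They cover counting error only, since reads without molecular identifiers are not independent molecules.

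Alternatives fixed before the data were examined covered scaling, the filter, duplicates, the choice and width of regions, the X chromosome, the libraries in the fit, a replicate block, equal depth and leaving out each library. Alternatives added later used reads of mapping quality 30 or more, 10 kb bins, another rule for duplicates, a limma trend, each sequencing run alone, regions with peaks at every age, the F of limma and, for the F test, other scaling, filters, reads and regions. The broad peak lists give no summit, so fixed windows were centred on the peak with the largest −log10 q. Promoters, 17 gene lists fixed in advance and sequence motifs were not analysed here, because no annotation or sequence of mm9 was used here; regions are given by coordinates, counted from 1.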

Results

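Accessible chromatin was profiled by ATAC-seq in cells positive for HopX, sorted by flow cytometry from mouse brain. HopX is a homeodomain-only protein known as a marker of radial glia and neural stem cells, and the labels call the cells neural progenitor cells of C57BL/6 mice. ATAC-seq uses the Tn5 transposase to insert sequencing adapters into open DNA, so that read ends mark accessible positions. The 7 libraries cover embryonic day 15 (E15, n = 2), postnatal day 3 (P3, n = 3) and adult (n = 2). The labels do not say whether the replicates of an age came from separate animals, and p-values measure only the spread between these samples, which may be technical. The deposited reads per library ranged from 2663653 (E15 replicate 2) to 11493295 (adult replicate 2). Distinct read positions ranged from 2417280 in E15 replicate 2 to 10571366 in P3 replicate 3.

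Fragments from adult cells were shorter than those from E15 and P3 cells. The median length of distinct autosomal fragments was 120 ± 2.83 bp in adult (SD, n = 2), 137 ± 9 bp at P3 (SD, n = 3) and 139 ± 8.49 bp at E15 (SD, n = 2). Fragments below 100 bp, the range of DNA free of nucleosomes, made up 39.8% ± 0.331 (SD, n = 2) in adult, 34.2% ± 2.22 (SD, n = 3) at P3 and 33.9% ± 2.39 (SD, n = 2) at E15. The longest fragments, beyond the range of 1 nucleosome, made up 7.06% ± 0.815 (SD, n = 2) in adult, 10.6% ± 2.24 (SD, n = 3) at P3 and 11.8% ± 0.688 (SD, n = 2) at E15. Both adult libraries lay outside the range of all E15 and all P3 libraries in each of these measures. They also had a higher density of chromosome Y reads than all of those libraries, so sex cannot be told apart from age. In the exact two-sided permutation test of adult against P3 the p was 0.2 for each measure, the smallest p that 2 against 3 libraries can give. Adult against E15 gave an exact permutation p of 0.333, also the smallest possible. In every library the abundance of fragments between 60 and 160 bp rose and fell with a period of 10.35 or 10.4 bp, close to the helical repeat of DNA. The crest stood 63.1% above the trough in adult replicate 3 and 89.2% in E15 replicate 1, the lowest and highest of the 7 libraries.

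**Figure D1:**
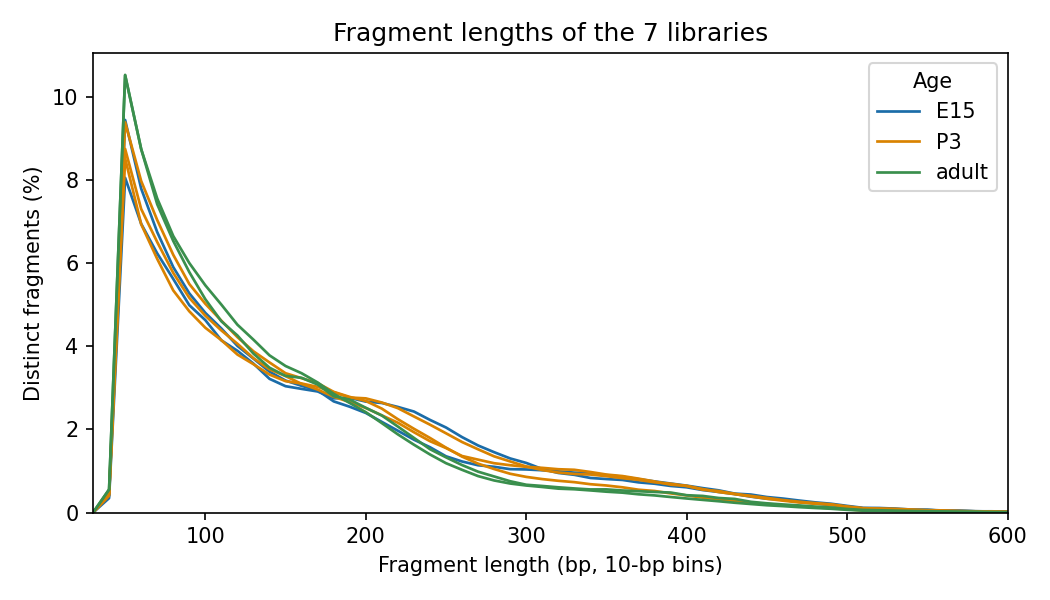
Share of distinct autosomal fragments (%) in 10-bp bins of fragment length (bp), with 1 line per library coloured by age. The 2 adult lines lie above the others from 40 to 100 bp and below them from 240 to 380 bp.

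The share of reads in peaks asks how much of each library fell in the accessible regions that the authors' peak lists define. Peaks of at least 2 libraries merged into 47288 autosomal regions with a median length of 424 bp, which cover 23.3 Mb, or 0.943% of the autosomes. They held 10.1% ± 2.42 (SD, n = 2) of distinct reads at E15, 7.28% ± 1.404 (SD, n = 3) at P3 and 8.58% ± 2.87 (SD, n = 2) in adult. The ages overlapped, with exact two-sided permutation p of 0.4 for P3 against E15, 0.6 for adult against P3 and 0.667 for adult against E15. The smallest possible values were 0.2, 0.2 and 0.333. Restricted to reads of mapping quality 30 or more, the shares were 0.656% ± 0.257 (SD, n = 2) at E15, 0.506% ± 0.0885 (SD, n = 3) at P3 and 0.442% ± 0.0474 (SD, n = 2) in adult, each below the 0.943% of the autosomes that the regions cover. With the reads as deposited, all 3 P3 libraries lay below both E15 libraries, at 10.8% ± 1.66 (SD, n = 3) against 14.8% ± 2.90 (SD, n = 2), with an exact permutation p of 0.2. With the peaks of each library alone the order of adult and P3 turned, at 13.1% ± 8.75 (SD, n = 2) at E15, 8.10% ± 3.62 (SD, n = 3) at P3 and 5.53% ± 1.002 (SD, n = 2) in adult. Both adult libraries then lay below both E15 libraries (exact permutation p = 0.333).

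Of the 12 regions with most reads, those with the highest shares at all 3 ages lay on chromosomes 9 and 2 of mm9. A region on chromosome 1 came next at E15 and P3, and in adult after 2 further regions of chromosome 9. The region on chromosome 9 from 3000026 to 3004774 held 0.291% ± 0.103 (SD, n = 2) of distinct autosomal reads at E15, 0.156% ± 0.0282 (SD, n = 3) at P3 and 0.231% ± 0.111 (SD, n = 2) in adult. That on chromosome 2 from 98506400 to 98507491 held 0.176% ± 0.0878 (SD, n = 2), 0.0958% ± 0.0158 (SD, n = 3) and 0.120% ± 0.0627 (SD, n = 2) in the same order. That on chromosome 1 from 24618423 to 24622983 held 0.137% ± 0.0645 (SD, n = 2), 0.0882% ± 0.0182 (SD, n = 3) and 0.0872% ± 0.0363 (SD, n = 2). These regions were chosen after their values were seen. Reads of mapping quality 30 or more made up 0.0988%, 0.740% and 1.07% of their reads. Over all regions such reads made up 3.18% ± 0.478 (SD, n = 2) at E15, 4.16% ± 0.311 (SD, n = 3) at P3 and 2.69% ± 1.15 (SD, n = 2) in adult. Outside the regions they made up 54.8% ± 0.879 (SD, n = 2), 63.9% ± 2.49 (SD, n = 3) and 53.3% ± 9.34 (SD, n = 2).

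**Figure D2:**
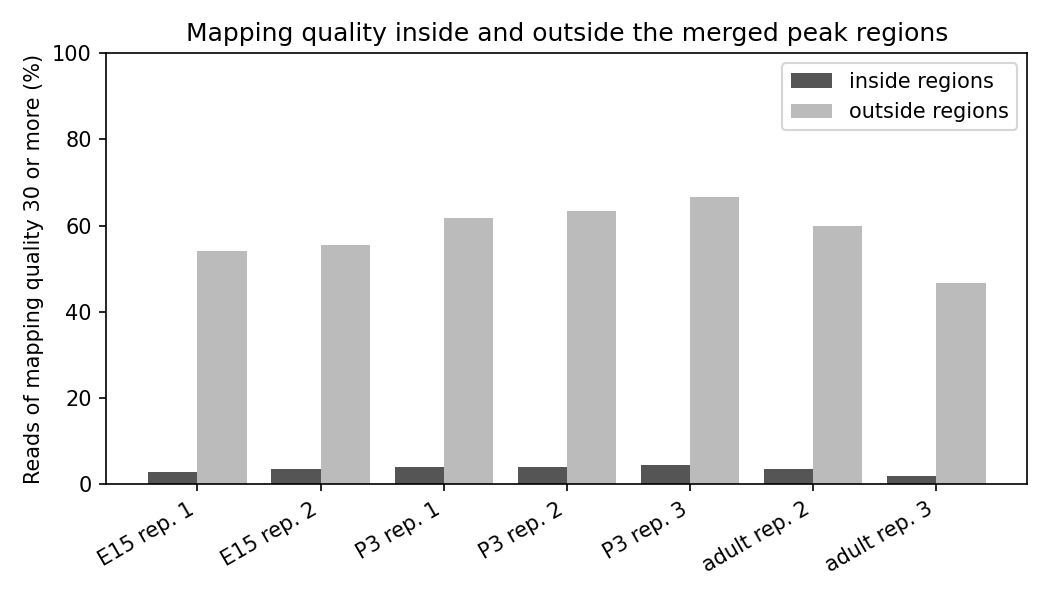
Percentage of distinct autosomal reads with a mapping quality of 30 or more inside (dark bars) and outside (light bars) the merged peak regions, per library. Inside the regions the share lies between 1.88% and 4.51%, and outside between 46.7% and 66.7%.

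The overlap of peak lists asks how far libraries of 1 age share accessible sites, compared with libraries of different ages. The authors' lists held 62674 ± 25142 peaks at E15 (SD, n = 2), 62375 ± 27935 at P3 (SD, n = 3) and 31568 ± 12135 in adult (SD, n = 2). Of the peaks of a library, 17.2% were overlapped by at least 1 base in another library of the same age (mean of 5 pairs, 10.97% to 21.5%). Between ages the mean was 14.7% over 16 pairs, with a range of 10.5% to 20.8%, and the ranges overlapped. The Jaccard index in bases averaged 0.0622 within ages and 0.0510 between ages. With peak positions shifted at random along each chromosome, the overlapped share was 0.863% on average over the 21 pairs. Peaks with a majority of reads of mapping quality 30 or more were overlapped in 1.03% of cases, and the other peaks in 20.1%.

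Regions were next sorted by the ages at which at least 2 libraries had a peak. At all 3 ages there were 1137 such regions. At E15 alone there were 2905, at P3 alone 16636 and in adult alone 1663. E15 and P3 shared 2724 further regions, P3 and adult 1615, and E15 and adult 191. P3 had 3 libraries, which gives it more pairs that can meet the rule. Leaving out P3 replicate 1, 2 or 3 lowered the P3 count to between 5113 and 10911, and the strongest 22987 peaks of each library gave 4928. With these equal numbers the order of E15 and adult turned, with 771 regions at E15 alone and 1786 in adult alone. The order of the shared regions turned too, with 268 for E15 and P3, 594 for P3 and adult and 85 for E15 and adult. Without P3 replicate 1 these were 1141, 702 and 462.

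The comparison of P3 with E15 asks which regions change in accessibility between embryo and newborn. Of 24963 regions tested, 3 were lower at P3 and 0 were higher (limma-voom, adjusted p under 0.05). The region on chromosome 8 from 119058342 to 119059149 had 11.7 ± 9.44 CPM at P3 (SD, n = 3) and 149 ± 56.6 at E15 (SD, n = 2), a log2 fold change of -4.03 (SE 0.75, limma adjusted p = 0.0358). These CPM rest on 2, 4 and 10 reads at P3 and 61 and 21 reads at E15. On chromosome 7 the region from 106445915 to 106447063 had 42.4 ± 31.1 at P3 (SD, n = 3) and 175 ± 2.03 at E15 (SD, n = 2), a log2 fold change of -2.30 (SE 0.43, limma adjusted p = 0.0358). On chromosome 12 the region from 117011599 to 117012641 had 39.0 ± 34.0 at P3 (SD, n = 3) and 144 ± 1.93 at E15 (SD, n = 2), a log2 fold change of -4.02 (SE 0.76, limma adjusted p = 0.0358). P3 replicate 1 had 0 reads there, and without it the log2 fold change was -1.32 (limma adjusted p = 0.945). None of the 3 calls held against leaving out each library. That on chromosome 8 was lost without any 1 of the 5 E15 and P3 libraries, at limma adjusted p from 0.0632 to 0.946 and log2 fold changes from -3.20 to -4.55. On chromosome 7 the call was lost without P3 replicate 3, at a log2 fold change of -1.63. It was also lost without E15 replicate 1 or 2, where 1 E15 library remained, at -2.33 and -2.31. On chromosome 12 the call was lost without any 1 P3 library, at -4.82 and -4.93 without P3 replicates 2 and 3. Without E15 replicate 2, where 1 E15 library remained and the call was also lost, the change there was -4.18. All 3 held no read of mapping quality 30 or more. In total 1097 regions, 4.39% of those tested, had an unadjusted p under 0.05. Without E15 replicate 2 or P3 replicate 3 the count was 1 or 0, and without E15 replicate 1, adult replicate 2 or adult replicate 3 it was 18, 19 or 22. Limma with an intensity trend called 6 regions, 5 of them higher at P3. Scaling by total reads gave 29 lower and 2 higher, with a median log2 fold change over all regions of -0.25 in place of 0.04, and factors from bins outside peaks gave 30 lower and 1 higher.

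The comparison of adult with P3 asks the same between the newborn and the mature brain. In adult 7 regions were higher and 0 were lower (limma-voom, adjusted p under 0.05). Both adult libraries had a higher density of chromosome Y reads than all 3 P3 libraries, so sex cannot be told apart from age here. The region on chromosome 15 from 88421268 to 88422239 had 122 ± 15.8 CPM in adult (SD, n = 2) and 22.4 ± 13.4 at P3 (SD, n = 3), a log2 fold change of 2.54 (SE 0.45, limma adjusted p = 0.0280). On chromosome 18 the region from 7322409 to 7323550 had 274 ± 98.6 in adult (SD, n = 2) and 28.5 ± 32.6 at P3 (SD, n = 3), a log2 fold change of 4.21 (SE 0.78, limma adjusted p = 0.0280). P3 replicate 2 had 0 reads there, and without it the log2 fold change was 2.89 (limma adjusted p = 0.00202). That call was lost without P3 replicate 1 (4.80, limma adjusted p = 0.697), P3 replicate 3 (5.33, limma adjusted p = 0.801) or adult replicate 2 (3.82, limma adjusted p = 0.0636). On chromosome 10 the region from 119330601 to 119332037 had 268 ± 160 in adult (SD, n = 2) and 54.7 ± 47.6 at P3 (SD, n = 3), a log2 fold change of 2.52 (SE 0.47, limma adjusted p = 0.0280). It was 1.74 without P3 replicate 3, where the call was lost (limma adjusted p = 0.170), 1.87 without adult replicate 3 and 3.37 without P3 replicate 1. The call on chromosome 15 was lost without P3 replicate 1, P3 replicate 3 or adult replicate 2, at log2 fold changes of 2.44, 2.89 and 2.41. Reads of mapping quality 30 or more made up 0% of the reads of the regions on chromosomes 15 and 10 and 4.73% of that on chromosome 18. In total 1227 regions, 4.92% of those tested, had an unadjusted p under 0.05. The count was 0 without P3 replicate 3, 3 without P3 replicate 1, 12 without E15 replicate 2, 31 without adult replicate 2 and 19 without adult replicate 3. Scaling by total reads gave 13 higher and 2 lower, limma with an intensity trend 6 higher and 3 lower, and reads as deposited 0 higher and 1 lower.

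**Figure D3:**
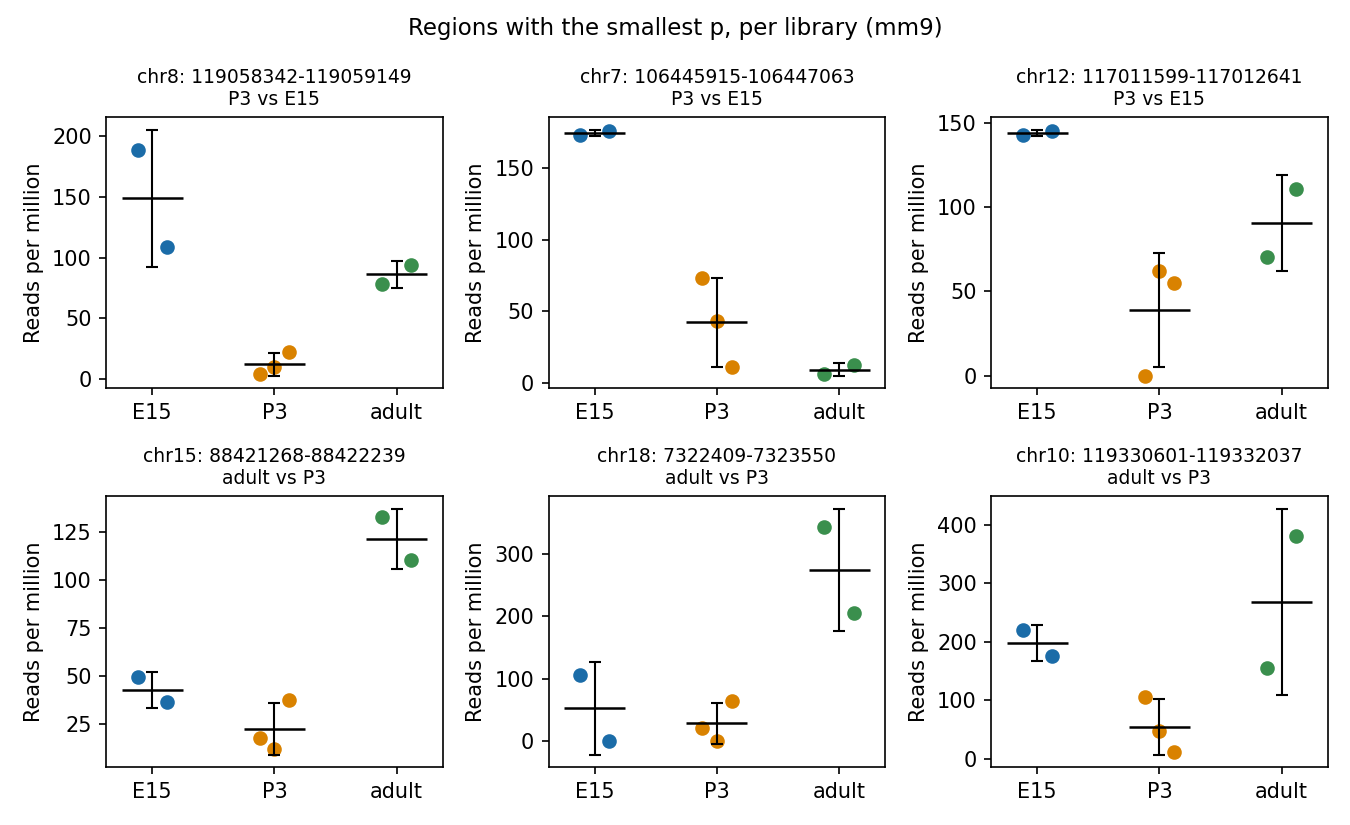
CPM in 6 regions (mm9), with 1 point per library, the mean as a line and the SD as an error bar. The upper 3 regions were lower at P3 than at E15 and the lower 3 were higher in adult than at P3, with every library of 1 age on the same side of every library of the other.

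The comparison of adult with E15 spans the whole age range. Both adult libraries had a higher density of chromosome Y reads than both E15 libraries, so sex cannot be told apart from age here either. Limma-voom called 0 of 24963 regions, with a smallest adjusted p of 0.804. At an unadjusted p under 0.05 there were 475 regions, 1.90% of those tested, and limma with an intensity trend called 4. The count was 4 without E15 replicate 1 and 1 without adult replicate 3. Scaling by total reads gave 17 regions, all lower in adult, with a median log2 fold change over all regions of -0.19 in place of 0.07. A fit of only the libraries of these 2 ages called 17, with 1 higher and 16 lower in adult. Fixed windows gave 7, all lower in adult.

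Tested across the 3 ages at once, 15 of 24963 regions differed (limma-voom, F test, adjusted p under 0.05). The smallest adjusted p was 0.0342, for the regions named on chromosomes 7, 10, 15 and 18. The F of limma itself gave 3 regions over 3 contrasts and 13 over 2 contrasts, both seen first, and 0 with an intercept in the design. Of 100 splits of the 7 libraries into groups of 2, 3 and 2, 23 gave at least as many regions as the ages. In a principal component analysis of log2 CPM, E15 replicate 2 stood alone on the first component (34.3% of variance) and adult replicate 3 on the second (18.3%). Without P3 replicate 3 the count was 0, and without E15 replicate 2 or P3 replicate 1 it was 5 or 3. Without E15 replicate 1, adult replicate 2 or adult replicate 3 it was 27, 30 or 43. Between libraries, log2 CPM over the tested regions correlated at a mean Spearman rho of 0.401 within ages (5 pairs, 0.306 to 0.451) and 0.374 between ages (16 pairs, 0.301 to 0.436). The pair of E15 libraries had the lowest value within ages, below 14 of the 16 pairs between ages. Every pair with E15 replicate 2, the library with fewest reads, lay between 0.301 and 0.342. E15 replicate 1 correlated at 0.350 to 0.436 with the P3 and adult libraries. These correlations are across regions, which are not independent replicates.

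Coverage of the 19 autosomes differed between libraries. Relative to the median of the 7 libraries, the density of read ends was 1.41 on chromosome 6 in E15 replicate 2 and 1.27 on chromosome 15 in adult replicate 3. Both of these libraries were low on chromosome 19 (0.757 and 0.749) and chromosome 12 (0.803 and 0.824). The SD over autosomes was lowest in P3 replicate 3, at 0.0479, and highest in E15 replicate 2, at 0.149.

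**Figure D4:**
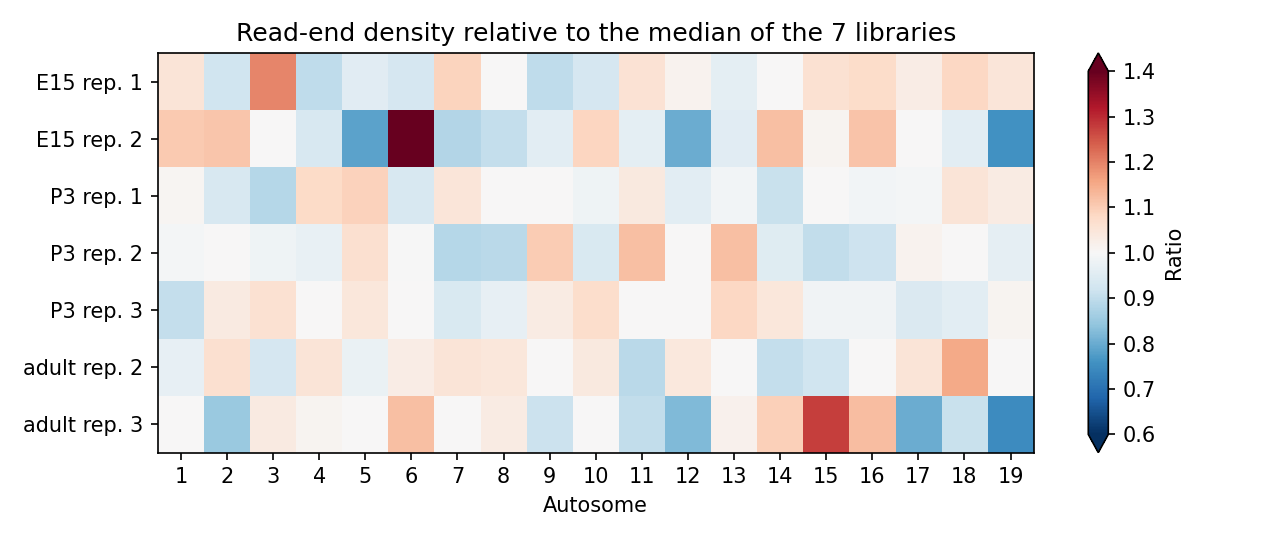
Density of read ends of mapping quality 30 or more on each of the 19 autosomes in the 7 libraries, as a ratio to the median of the libraries. The most uneven value is 1.41, on chromosome 6 in E15 replicate 2.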

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

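The tests of mapping quality inside regions, of bins, of correlation between ages and of distinct read ends were chosen after the results were seen. Reads of chromosome Y and of the mitochondrial genome entered no test of regions. On chromosome Y, distinct read ends of mapping quality 30 or more numbered 1407 in adult replicate 2, 483 in adult replicate 3 and 326 in E15 replicate 1. They numbered 19, 30 and 28 in P3 replicates 1, 2 and 3, also above the 3 that a count of 0 allows, and 3 in E15 replicate 2. These counts are not scaled for depth. Relative to autosomes the density was 0.00418 in E15 replicate 2 and 0.00640 to 0.0113 at P3. The counts thus do not separate E15 replicate 2 from P3, and misplaced reads were not tested. The mitochondrial genome held 0.781% ± 0.353 of reads at E15 (SD, n = 2), 0.761% ± 0.269 at P3 (SD, n = 3) and 0.468% ± 0.0704 in adult (SD, n = 2).

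Few regions differed between ages, 15 across all 3. A candidate explanation is too few reads and libraries: at most 15.4% of simulated 4-fold changes were recovered in any comparison. The simulation kept the reads, libraries, spread and test fixed. It thus cannot tell too few reads and libraries apart from the spread or the test. Chance cannot be excluded either, since 23 of 100 splits of the 7 libraries into groups of 2, 3 and 2 gave at least as many regions and the highest other split gave 74, several times the real count, which points to a structure of the samples. E15 replicate 2 and adult replicate 3 each stood alone on 1 of the first 2 principal components (34.3% and 18.3% of variance). These 2 libraries had the fewest distinct read positions, 2417280 and 3350276, against 5487399 or more in the others. Depth thus cannot be told apart from another structure. Libraries that did not stand alone also moved the count, from 15 to 0 without P3 replicate 3 and to 3 without P3 replicate 1. Bins of 10 kb with reads of mapping quality 30 or more gave 2 calls. The limit written for this test would count so few calls against reads of low mapping quality as a cause. A condition on recovery, added after the value was seen, leaves it open. That recovery was simulated for the regions and not for the bins. Whether accessible chromatin is alike at the 3 ages cannot be told apart from noise, at a mean correlation over those bins of 0.0937 between ages and 0.122 within ages; over bins of 1 Mb it was 0.142 between and 0.275 within ages.

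The regions rest on reads of low mapping quality. The share of reads of mapping quality 30 or more inside regions was at most 0.0677 of that outside, in any library, which is consistent with reads placed among repeated copies of a sequence. Open chromatin at single-copy sites stays open as a further source: at peaks made mostly of reads of mapping quality 30 or more, other libraries had a median density 1.38 times that of the 5 kb on either side, between the limits of 1.2 and 1.5 set before the test.

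Chromosomes were unevenly covered. E15 replicate 2 had 1.41 times the median density on chromosome 6, and E15 replicate 2 and adult replicate 3 had 0.757 and 0.749 times on chromosome 19. Differences between the 2 sequencing runs are argued against, since the ratios of the 19 autosomes correlated at 0.9965 or more between runs in every library. The spread over autosomes was larger in libraries with fewer distinct read ends (Spearman rho = -0.893, exact permutation p = 0.0123, n = 7). Pearson r was -0.882 (exact permutation p = 0.0087), and -0.922 without the 2 libraries farthest from the median. In every library the spread far exceeded that from counting alone. It was 0.149 against 0.00558 in E15 replicate 2 and 0.0479 against 0.00230 in P3 replicate 3. Counting of fewer distinct read ends thus does not account for the size of the spread. What else goes with their number was not tested. Libraries of 1 age differed, at 0.0780 and 0.149 at E15 and 0.0639 and 0.127 in adult, and age stays open as untested.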

How the results depend on the processing

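Several alternatives were added after seeing the data: mapping quality 30 or more, 10 kb bins, duplicates by 5-prime end, the limma trend, each sequencing run alone, regions with peaks at every age the F of limma and, for the F test, other scaling, filters, reads and regions. Of the 6 regions named, none changed sign under an alternative that gave them a value. Each lost its call under between 5 and 10 of those 22 or 23 alternatives. The named regions had no value under mapping quality 30 or more, 10 kb bins, fixed windows or peaks with q under 0.001. Regions were matched by chromosome and start. Bins and fixed windows start elsewhere, so the same places may have been tested there without being matched. For regions with peaks at every age, only those on chromosomes 12 and 10 had a value. The cause of the changes below was not tested, except that thinning left 3430 regions to test, peaks with q under 0.001 left 702 and mapping quality 30 or more left 116.

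Counts are given in the order P3 against E15 (3), adult against P3 (7) and adult against E15 (0). Total reads gave 31, 15 and 17, and factors from bins outside peaks gave 31, 11 and 16; the median log2 change moved from 0.04, 0.06 and 0.07 to -0.25, 0.07 and -0.19, and to -0.34, 0.11 and -0.25. Fixed windows gave 15, 1 and 7. Only the libraries of the 2 ages gave 17, 13 and 17. Bins of 10 kb gave 0, 1 and 1. The first sequencing run gave 11, 1 and 3, and the second 0, 0 and 0. The limma trend gave 6, 9 and 4. Reads as deposited gave 0, 1 and 0, and the 1 region was lower in adult, against the direction of the 7. Peaks of 1 library or more gave 13, 12 and 0. The X chromosome included, they were 6, 14 and 0. No filter gave 5, 10 and 0. Duplicates by 5-prime end gave 8, 10 and 0. Mapping quality 30 or more gave 0, 4 and 0. Regions with peaks at every age gave 1, 0 and 0. Thinning and peaks with q under 0.001 each gave 0, 0 and 0. Leaving out 1 library gave 0 to 22, 0 to 31 and 0 to 4; where 1 library of an age remained, it was assumed to vary like the others.

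With the replicate block the counts were 51 (3 higher, 48 lower), 18 (14 higher, 4 lower) and 13 (6 higher, 7 lower). The labels link equally numbered samples by the number alone. Their deviations correlated at -0.0477 to 0.0031 over 5 pairs. Libraries correlated only in part even within ages, so these values cannot exclude a shared preparation.

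Across the 3 ages (15), total reads and factors from bins outside peaks each gave 58, no filter 36, peaks of 1 library or more 25, fixed windows 24, overlap by 50% of the smaller peak 1, and reads as deposited, thinning and peaks with q under 0.001 each 0. Duplicates by 5-prime end gave 26, the limma trend 9, regions with peaks at every age 5, mapping quality 30 or more 2, bins 2 and the second sequencing run 0. The F of limma gave 3 over 3 contrasts, 13 over 2 contrasts and 0 with an intercept. Leaving out 1 library gave 0 to 43.

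The share of reads in peaks at E15 was 13.1% for own peaks, 14.8% as deposited and 0.656% for mapping quality 30 or more. At P3 it was 10.8% as deposited and 0.506% for mapping quality 30 or more. In adult it was 5.53%, 13.2% and 0.442%. Leaving out 1 library gave 8.34% to 11.8% at E15, 6.74% to 8.08% at P3 and 6.55% to 10.6% in adult. The strongest peaks, equal in number, gave an overlap of 11.8% within and 10.2% between ages. Overlap by 50% of the smaller peak gave 11.8% between ages. Leaving out 1 library gave 14.5% to 18.7% within and 13.8% to 15.6% between ages. The strongest peaks gave 391 regions at all 3 ages, 771 at E15 alone, 4928 at P3 alone and 1786 in adult alone. Leaving out a P3 library gave 761 to 979, 3503 to 4202, 5113 to 10911 and, in adult alone, 2018 to 2457. Leaving out an E15 or adult library gave no value, since 2 libraries with a peak were required. The planned second count tool, promoters, gene lists and motifs were not run.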

Other observations

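The tests of the shares below were chosen after the values were seen, and that of the mitochondrial stretch before. A hypothesis is that the chromosome 1 region from 24618423 to 24622983 (4561 bp) holds a copy of mitochondrial sequence. Its share of deposited reads followed the mitochondrial share over the 7 libraries (Pearson r = 0.997, Spearman rho = 1, exact permutation p = 0.0004 each, adjusted p = 0.0048 over 12 regions). Without the 2 libraries farthest from the median r was 0.9996. With distinct reads for both shares r was 0.9987 and rho 1 (exact permutation p = 0.0004 each), and with distinct reads for the region alone r was 0.722 (exact permutation p = 0.0524). The test as written named 1 mitochondrial stretch, and 13 were found where most reads had a mapping quality under 10. The longest, from 6451 to 11000 (4550 bp), was used; in it 98.1% of reads had a mapping quality under 10, while 79.1% of reads elsewhere had 30 or more. Both results are consistent with the hypothesis, which no sequence comparison was run to test. Of deposited reads the region held between 24.9 and 27.0 reads per 100 mitochondrial reads in every library.

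The density of chromosome Y read ends relative to autosomes was 0.311 and 0.444 in the adult libraries, 0.152 and 0.00418 in E15 replicates 1 and 2, and 0.00640 to 0.0113 at P3. The density on chromosome X was 0.870 and 0.823 in adult, 0.968 and 1.15 at E15 and 0.778 to 0.954 at P3. The labels give no sex. Both adult libraries lay above all E15 and P3 libraries on chromosome Y. A difference in sex thus cannot be told apart from age in the comparisons of adult with P3 or with E15.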
